A study of Mus musculus with 25 samples.

How the data were processed

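CD11b+ cells from mouse kidneys were sorted by Ly6C into High, Intermediate and Low gates after 28 min of bilateral ischemia and 4 h, 24 h or 9 days of reperfusion, or after sham surgery. Per the labels, RNA was amplified with a whole-transcriptome kit for picogram amounts and hybridised to Affymetrix mouse arrays with 45101 probe sets. The labels give 1 array per animal and gate, except 3 arrays of sham 58 High. Of 25 arrays 21 in 8 groups entered the model. The other 4 stayed out. They were 3 arrays that share the label sham 58 High, which does not tell whether they are separate animals, and 1 array of reference RNA. One 4 h High array (replicate 30) carries a second description line that names 9 days and was kept in the group its title gives. The series text names later and further sham groups that no label shows, and these were not analysed here.

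The log2 values, as deposited, were made by the authors with RMA (background correction, quantile normalization and summary per probe set, per the labels; version not given). The signal intensities were deposited on a linear scale with a trimmed mean (2%) of 500 on every array, in the form of MAS5 output; the algorithm is not given in the sources used here. The deposited detection calls are the letters P, M and A per probe set, and they set the filter. The share of probe sets called P measures the yield of each array, from 1.99% to 40.0% over the 21 arrays, and the arrays under 5% are called arrays of low yield. The 3' to 5' ratios of Gapdh and actin are ratios of the deposited signals of their control probe sets. The number of arrays per group limits the precision.

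Gene symbols came from the probe table, by Entrez ID where one was given. Of the probe sets 34958 had exactly 1 gene and covered 18194 genes; 932 had several genes and 9211 were not listed. For a gene with several probe sets the one with the highest mean over the 21 arrays was kept. A gene was tested if its probe set was called P on at least 2 arrays of at least 1 group, which left 8341 genes.

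A group-means model was fitted to the log2 values of the 21 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes; 13 residual degrees of freedom, 3.93 prior degrees of freedom, median residual SD 1.64). The 13 comparisons between groups, the 2 differences of effects and the F test over the Intermediate groups were adjusted by Benjamini-Hochberg over all genes tested, two-sided, with calls at adjusted p under 0.05 and no minimum fold. Each ± beside a log2 difference is the standard error from the model, and each ± beside a group mean is the SD between arrays. Where a group had no array with the probe set called P, its fold is marked "at least". It was computed with the values of that group raised to at least the lowest value called P on each array. This floor can lie near background: Itgam was called P at 2.14 on 24 h Intermediate replicate 7. Such a fold can therefore equal the fitted fold. It leaves out the spread between arrays and is not a minimum for the true fold. The animal was not a term of the model: the residuals of arrays of the same animal correlated at -0.07 to 0.06, and models with the animal as a fixed or random block were alternatives.

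Gene lists written for 24 cell types and processes were tested with camera (preset correlation 0.01; higher or lower relative to the other genes tested), with Benjamini-Hochberg over the lists of a comparison. Calls were repeated with an estimated correlation and with fry. The lists were classical monocyte, nonclassical monocyte, tissue macrophage, antigen presentation by MHC class II, pro-inflammatory mediators, alternative activation, chemokine receptors, interferon-stimulated genes, hypoxia and glycolysis, oxidative phosphorylation, matrix remodelling, efferocytosis and lysosome, cell cycle, immediate early genes, neutrophil, NK cell, T cell, B cell, dendritic cell, eosinophil and mast cell, kidney tubule, endothelial cell, fibroblast and mural cell, and erythrocyte and platelet.

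Named genes followed a rule: among genes with adjusted p under 0.05, an absolute log2 difference of at least 1 and no overlap between the values of the groups, those with the largest difference in each direction (up to 12, in that order, leaving out uninformative symbols); for each list described up to 4 members of smallest p; and for the F test and the differences of effects the 10 genes of smallest p. The groups, comparisons, tests, lists, naming rule and the following alternatives were set before the data were examined. They were the deposited signals (log2 of signal plus 1), quantile normalization, centring on the array median, no filter, detection on every array of a group, the mean of probe sets, only the groups compared, array weights, a variance trend with a robust prior, the animal as a fixed or random block, the mean of the sham 58 arrays added to sham High, removal of other-cell-type genes, and leaving out each array in turn. Models without the 3 arrays of low yield, and with the share of probe sets present as a covariate, were added after the detection calls were seen. Lists were tested with this covariate in 3 comparisons (9 day Intermediate against Low, and 9 days against sham in each gate).

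The pipeline was tested on simulated data with 200 changed genes at the group sizes and residual spread used here. It recovered 45.5% to 86.4% of genes changed by 8 (log2), 4.48% to 32.8% by 4 and up to 5.97% by 2. False calls numbered 1 to 5, but 14 of 96 for 9 days against 24 h. Real arrays differed in yield and other splits of them gave up to 221 calls, so these rates need not hold there. Principal components used the 1000 genes of highest variance, and correlations with array yield 100000 two-sided permutations. Correlation between arrays (across genes, not independent replicates) had a median of 0.657 within and 0.578 between groups.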

Results

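Gene expression was measured on mouse whole-genome arrays in CD11b+ myeloid cells sorted from kidneys of male C57BL/6 mice aged 8 to 10 weeks. The mice had 28 min of bilateral renal ischemia followed by reperfusion, or a sham operation without clamping. Cells were sorted into gates by surface Ly6C, a protein abundant on inflammatory monocytes and low on resident macrophages. The 21 arrays compared here fell into 8 groups. The 5 injured groups had 3 arrays each and were 4 h Ly6C High, 4 h Ly6C Intermediate, 24 h Ly6C Intermediate, 9 day Ly6C Intermediate and 9 day Ly6C Low. Sham High, sham Intermediate and sham Low had 2 arrays each, and the time after sham surgery is not given in the sources used here.

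Detection differed widely between arrays. The share of the 45101 probe sets called present averaged 31.8% ± 6.04 (SD, n = 3) in 9 day Low and 33.7% ± 8.92 (n = 2) in sham Low. It averaged 19.0% in sham Intermediate, 17.3% in 4 h High and 13.6% in 24 h Intermediate, and ran from 11.9% to 17.7% in 4 h Intermediate. Sham High held 1 array at 1.99% and 1 at 12.9%. Among the 9 day Intermediate arrays, replicates 8, 13 and 9 reached 3.29%, 4.67% and 25.5%. The 3 arrays under 5% are called arrays of low yield. The ratio of 3' to 5' signal of the Gapdh control probe sets, which rises as RNA or its amplified copy is shortened, was 298 and 28.3 in sham High and 431 and 3.93 in sham Intermediate (replicates 1 and 2). It lay between 1.85 and 2.82 in sham Low, 2.56 and 19.7 in 4 h High, 6.81 and 10.5 in 4 h Intermediate, 3.30 and 10.0 in 24 h Intermediate, 0.92 and 8.16 in 9 day Intermediate and 3.00 and 10.7 in 9 day Low. The same ratio for actin was 183 in sham Intermediate replicate 1, 51.8 and 22.1 in the 9 day Intermediate arrays of low yield and 13.4 or less elsewhere. The first principal component of the 1000 most variable genes carried 32.4% of the variance. It followed the share of probe sets present over the 21 arrays with Pearson r = -0.83 (permutation p = 2.0e-05) and Spearman rho = -0.95 (permutation p = 1.0e-05, the smallest the permutations can give). Without the 2 arrays farthest from the median share r was -0.87. Of 2 components tested, adjusted p was 4.0e-05 for r and 2.0e-05 for rho for this one. The second had r = 0.44 (permutation p and adjusted p = 0.0474) and rho = 0.42 (0.0582), and r = 0.34 without the same 2 arrays. Over the 18 arrays above 5% it followed the share with r = 0.77 (permutation p = 4.7e-04) and rho = 0.86 (permutation p = 2.0e-05), and the first with r = -0.85 and rho = -0.92 (permutation p = 1.0e-05 each).

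**Figure D1:**
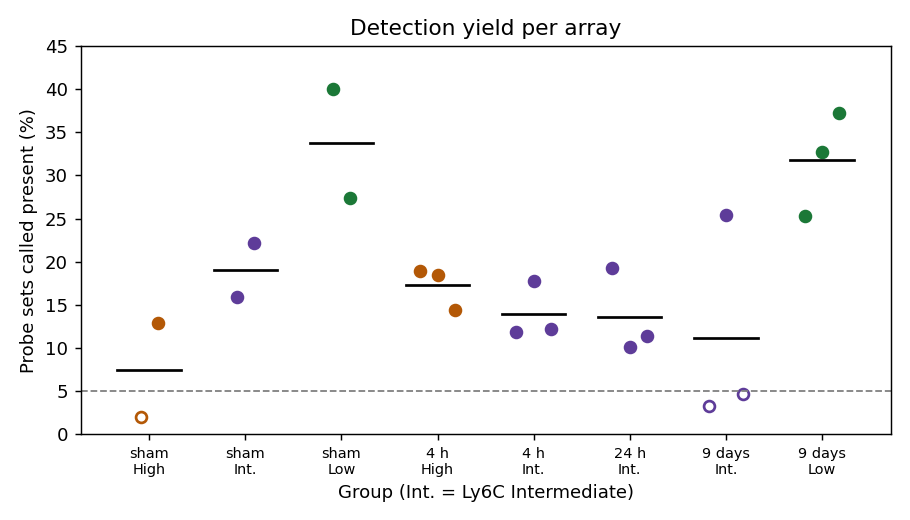
Share of probe sets called present (percent, vertical axis) on each of the 21 arrays by group, with a bar at the group mean and a dashed line at 5%. Open circles are the 3 arrays of low yield, at 1.99%, 3.29% and 4.67%.

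The probe set shared by Ly6c1 and Ly6c2, the genes of the sort marker, gave 12.59 ± 0.26 (log2, SD, n = 3) in 4 h High and 11.45 ± 0.80 in 4 h Intermediate. Its mean was 11.12 ± 0.12 in 24 h Intermediate and 4.77 ± 0.46 in 9 day Low (n = 3 each). In 9 day Intermediate 1 of 3 arrays was called present, at 10.92. The signal did not follow the gate labels of the sham arrays: it was 10.37 and 12.57 in sham Low, 10.26 and 11.66 in sham Intermediate, and in sham High 12.03 on 1 array and 2.83, called absent, on the array of low yield. Whether the sham Low labels are right is not settled by the sources used here. The probe set for Itgam, which encodes CD11b, stayed at group means between 2.58 and 4.08.

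**Figure D2:**
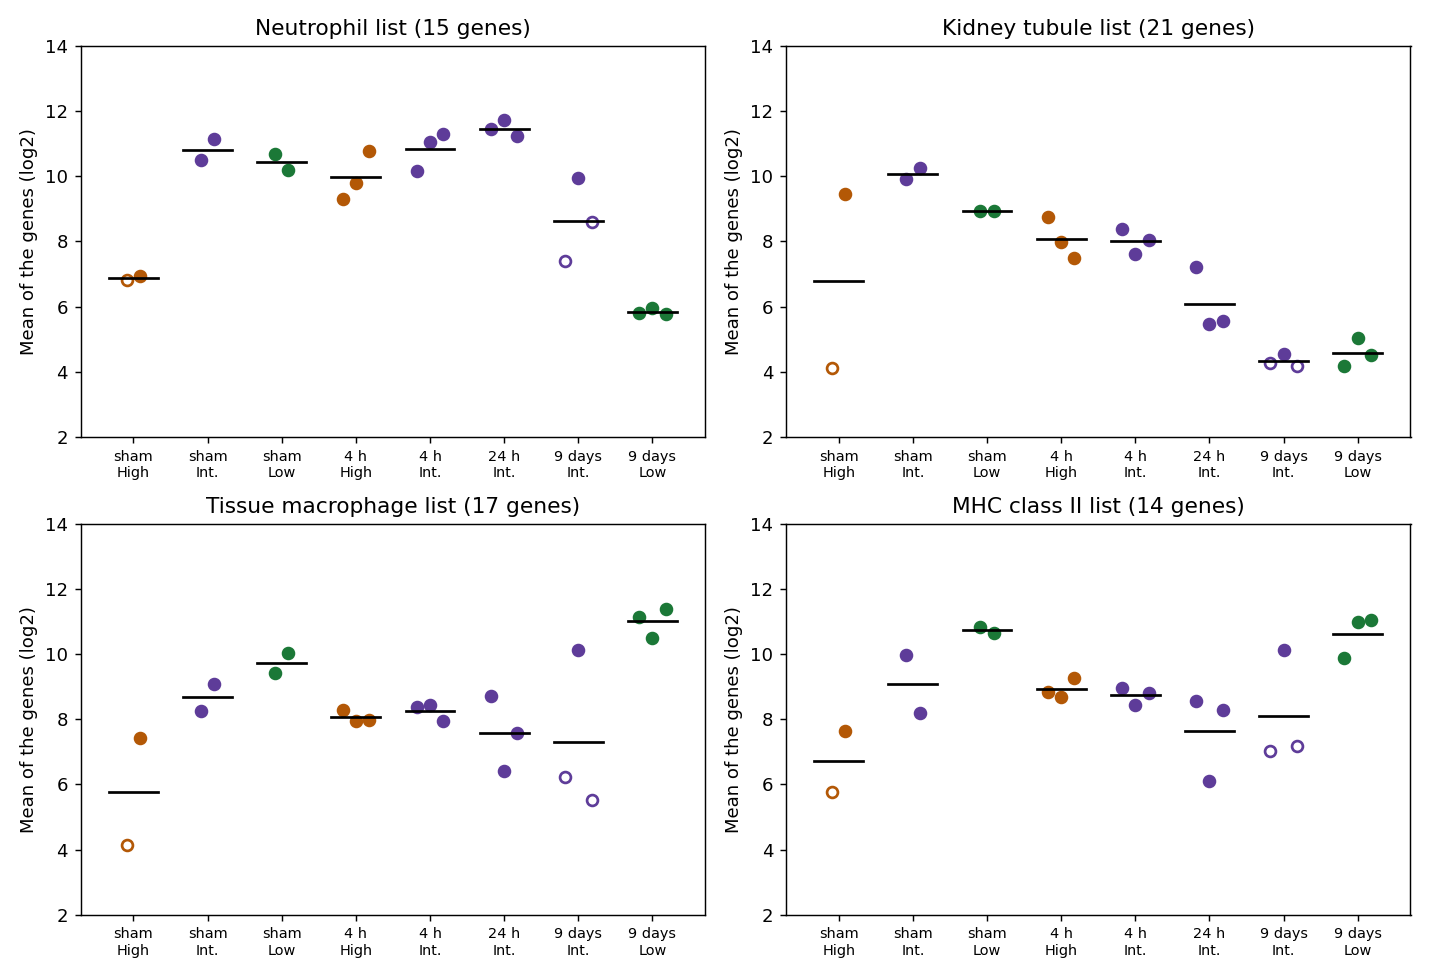
Mean log2 value (vertical axis) of the tested genes of 4 marker lists on each of the 21 arrays by group, with a bar at the group mean and open circles for the arrays of low yield. The neutrophil mean was 5.84 in 9 day Low and 11.47 in 24 h Intermediate, and the tubule mean was 10.08 in sham Intermediate and 4.33 in 9 day Intermediate.

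The kidneys sampled at 4 h gave both a Ly6C High and a Ly6C Intermediate fraction (n = 3 each), and the comparison asks whether the 2 gates differ in expression. The classical monocyte list leaned to the High gate and passed its test only under some models: 15 of its 16 tested genes lay above 0, with a median log2 difference of 0.87 against 0.14 over all genes, and camera gave adjusted p = 0.133, or 0.0222 with the animal as a fixed block. The neutrophil list leaned to the Intermediate gate, with 13 of 15 genes below 0 (median -0.79), at adjusted p = 0.0570, or 0.00499 with the animal as a fixed block; both lists had adjusted p = 0.964 with an estimated correlation and no block. Members of the classical monocyte list with the smallest p were Vcan, a matrix proteoglycan made by monocytes, at 4.03 ± 1.60 (log2 difference ± SE), F13a1, a transglutaminase subunit, at 5.67 ± 2.53, and Ccr2, the receptor that brings monocytes into tissue, at 2.51 ± 1.26. Usp18, a protease that removes ISG15 from proteins, was 5.81 ± 1.07 higher in High cells, with adjusted p = 0.166 over all genes and 8.33e-04 adjusted over the list alone of 18 interferon-stimulated genes. Ier2, an immediate early gene, was 3.19 ± 0.76 higher, with adjusted p = 0.283 over all genes and 0.0138 adjusted over the list alone. Their lists did not share these rises: the median was 0.26 for interferon-stimulated genes and -0.37 for immediate early genes, and neither list was called. Adjustment over 1 list alone takes no account of the other lists and comparisons. In limma 0 of 8341 genes passed, while 500 had an unadjusted p under 0.05. The count became 1 without High replicate 30 or 32, 4 without High replicate 33 and 3 without Intermediate replicate 32. With the animal as a fixed block it was 0, with 495 at an unadjusted p under 0.05. Camera called 0 of 24 lists without the block, and classical monocyte and neutrophil with it. When the 3 arrays of low yield, all from other groups, were left out of the model the adjusted p was 0.0251 for classical monocyte, 0.00651 for neutrophil and 0.0251 for pro-inflammatory mediators (median -0.50).

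At 9 days the Ly6C Intermediate cells differed from the Ly6C Low cells of the same kidneys (n = 3 each) by a neutrophil-like set of transcripts. Stfa2l1, a stefin that inhibits cysteine proteases, was higher by 6.37 ± 0.98 (log2, adjusted p = 0.00942). G0s2, an inhibitor of triglyceride lipase, was higher by 6.33 ± 1.06 (adjusted p = 0.0159). Of the 15 neutrophil genes 14 lay above 0, with a median of 2.81 against -1.24 over all genes. Of them 2 were higher over all genes and 7 adjusted over the list alone, among them the alarmins S100a8 (1.98 ± 0.55) and S100a9 (1.94 ± 0.55). Camera called this list at adjusted p = 1.55e-15, and adjusted p = 0.00368 with an estimated correlation. The largest deficits in Intermediate cells were in Sbf2, a phosphatase-like trafficking regulator, at least 152-fold lower, Macf1, a cytoskeletal crosslinker, at -6.72 ± 1.08, Sec22b, a vesicle SNARE, at least 102-fold lower, and Lhfp, at least 79.6-fold lower. Here and below, a fold marked "at least" is a point estimate made with the detection floor described above. It is not a lower bound for the true fold. Without the arrays of low yield, which leaves 1 Intermediate array here, the log2 differences of Sbf2, Macf1 and Sec22b were -7.35 ± 1.61, -6.01 ± 1.62 and -6.78 ± 2.27 (-7.25 ± 1.29, -6.72 ± 1.08 and -6.67 ± 1.45 with them). Their calls ended as the SE grew with fewer arrays, at adjusted p = 0.0903, 0.187 and 0.373, and Lhfp stayed under the threshold (0.0237). Stfa2l1 and G0s2 were then at 9.07 and 7.87.

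Macrophage genes were lower in 9 day Intermediate cells than in 9 day Low cells, in a model that leaves array yield out. In the tissue macrophage list 16 of 17 genes lay below 0 (median -3.37), with 0 lower over all genes and 10 adjusted over the list alone. Examples were Mertk, a receptor for dying cells, at least 45.8-fold lower, and the complement genes C1qa (-5.73 ± 1.58) and C1qc (-5.72 ± 1.60). The call at adjusted p = 3.07e-04 was lost with an estimated correlation (adjusted p = 0.489), and the median was -0.71 without the arrays of low yield. C1qa and C1qc were then at -1.42 and -1.35, Lpl at -0.94 and Sdha at -1.75. The efferocytosis and lysosome list (23 of 25 below 0, 6 adjusted over the list alone, Lpl -5.66 ± 1.49) had adjusted p = 0.0191, and adjusted p = 0.686 with an estimated correlation. The antigen presentation list (13 of 14 below 0, H2-Oa at least 14.8-fold lower) had adjusted p = 0.0408, 0.0571 with the animal as a fixed block, and adjusted p = 0.686 with an estimated correlation. Oxidative phosphorylation (30 of 32 below 0, Sdha -4.69 ± 1.20) had adjusted p = 0.0191, and adjusted p = 0.769 with an estimated correlation. Without the arrays of low yield the medians of these 3 lists were 0.13, -0.11 and -0.32. The share of probe sets present as a covariate ended all 4 calls, with medians of -0.54 for tissue macrophage (adjusted p = 0.248), 0.06 for efferocytosis (0.966), -0.15 for antigen presentation (0.877) and 0.32 for oxidative phosphorylation (0.877). Classical monocyte (median 0.50), kidney tubule (0.40), endothelial cell (0.48) and eosinophil and mast cell (2.70) were called as higher relative to the other genes. Their adjusted p with an estimated correlation was 0.686, 0.686, 0.293 and 0.293. In 9 day Intermediate 0 of the 8 endothelial genes and 0 to 4 of the 21 tubule genes were detected on an array, so these 2 lists lay near background there. With the covariate the endothelial (0.06, adjusted p = 0.966) and tubule (1.02, 0.0624) calls ended. The other 2 stayed, and nonclassical monocyte (1.76, 0.0432) and cell cycle (-0.69, 0.0317) were called. None of these 4 calls held with an estimated correlation (adjusted p from 0.128 to 0.553). In all 52 of 8341 genes passed in limma, 3 higher and 49 lower in Intermediate cells; quantile normalization gave 5 and 10, and centring gave 2 and 0. The count was 27 without the arrays of low yield (20 higher, 7 lower), 16 without Intermediate replicate 8, 8 without Intermediate replicate 13, 1290 without Intermediate replicate 9 and 27 without Low replicate 9. With the animal as a fixed block limma passed 0 genes, with 1410 at an unadjusted p under 0.05.

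The sham arrays were compared by their gate labels (n = 2 arrays each), which the sort marker did not follow. In sham High several transcripts were lower than in sham Intermediate. The Gapdh 3' to 5' ratio was 28.3 or more on 3 of these 4 arrays. Ifitm1, an interferon-induced membrane protein, was at least 716-fold lower in High cells. Stfa2l1 was at least 330-fold lower, Arg2, the mitochondrial arginase, at least 215-fold, Wfdc21, a whey-acidic-protein family member, at least 205-fold, and Lmnb1, a nuclear lamin, at least 196-fold. In the neutrophil list 14 of 15 genes lay below 0, with 1 lower over all genes and 8 adjusted over the list alone. Its camera call (adjusted p = 2.46e-06) had adjusted p = 0.126 with an estimated correlation. In the pro-inflammatory list 12 of 18 lay below 0 (median -5.04), with Il1b lower over all genes (-5.60 ± 1.14) and 10 adjusted over the list alone, among them Socs3 (-7.52 ± 1.74) and Ccl4, at least 100-fold lower. Its call (adjusted p = 6.40e-04) had adjusted p = 0.600 with an estimated correlation. Immediate early genes followed with 18 of 23 below 0 and 7 adjusted over the list alone, such as Fos (-4.33 ± 1.10); camera called them, with adjusted p = 0.622 with an estimated correlation.

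Other lists called as lower in sham High than in sham Intermediate leaned on the array at 1.99%. Kidney tubule (20 of 21 below 0, Lrp2 -5.63 ± 1.16 over all genes and adjusted over the list alone) had adjusted p = 5.37e-05, and adjusted p = 0.600 with an estimated correlation. Oxidative phosphorylation (31 of 32 below 0) had adjusted p = 9.06e-06, and adjusted p = 0.622 with an estimated correlation. Tissue macrophage (16 of 17 below 0) and antigen presentation (13 of 14 below 0) had adjusted p = 0.0191 and 0.0274 (0.0167 and 0.102 with the animal as a fixed block), and each adjusted p = 0.622 with an estimated correlation. Without the arrays of low yield the medians of these 4 lists were -0.39, 0.05, -1.13 and -1.49. In limma 28 genes passed, 0 higher and 28 lower, and 16 with the mean of the sham 58 arrays added to sham High, when the tissue macrophage, antigen presentation and immediate early calls ended (adjusted p = 0.181, 0.324 and 0.181); quantile normalization gave 3 and 26. Without the arrays of low yield 72 passed, 21 higher and 51 lower, while Il1b (-3.57, adjusted p = 0.0793) and Lrp2 (-4.22, 0.236) did not, and Fos was at -2.92. The count was 10 without High replicate 1, 386 without High replicate 2 and 13 without Intermediate replicate 2. A fixed block for the animal left 0 genes in limma, with 589 at an unadjusted p under 0.05.

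The arrays labelled sham Intermediate and sham Low (n = 2 each), with sort marker means of 10.96 and 11.47, differed in 6 genes in limma. Higher in Intermediate were Hdac2, a histone deacetylase, by 7.13 ± 1.13 (log2, adjusted p = 0.0305), Gstt3, a glutathione transferase, at least 34.1-fold, and Fam83h by 4.76 ± 0.73. Higher in Low were Nudt12, a peroxisomal nucleotide hydrolase, with the difference at least 24.1-fold, Cav1, the coat protein of caveolae, at -4.40 ± 0.78, and Dnase1l3, a secreted nuclease of macrophages and dendritic cells, at least 20.8-fold. The dendritic cell list was lower in Intermediate cells: 13 of 14 below 0, median -2.25, with 0 lower over all genes and 2 adjusted over the list alone, Btla (at least 14.9-fold) and Dpp4 (at least 134-fold). Its call (adjusted p = 0.00303) had adjusted p = 0.303 with an estimated correlation. Kidney tubule genes were called as higher, 16 of 21 above 0 with a median of 1.02 against -0.58 over all genes, at adjusted p = 3.92e-04, and adjusted p = 0.861 with an estimated correlation. Of the 6 genes 3 were higher and 3 lower; quantile normalization gave 1 and 0, and centring gave 1 and 0. Without the arrays of low yield 45 genes passed. Without Intermediate replicate 1 the count was 1, without Intermediate replicate 2 or Low replicate 2 it was 0, and without Low replicate 1 it was 12. With the animal as a fixed block limma passed 0 genes, with 800 at an unadjusted p under 0.05.

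Between the arrays labelled sham High and sham Low (n = 2 each) 7 genes passed in limma, all lower in High; the Gapdh 3' to 5' ratios were 298 and 28.3 in High and 1.85 and 2.82 in Low. Ifitm1 was at least 419-fold lower, Stfa2l1 at least 270-fold, Rab31, a trafficking GTPase, at least 229-fold, and Tprgl, a presynaptic scaffold protein, at least 128-fold. Cxcr4, the receptor that retains leukocytes in marrow, was lower by -6.37 ± 0.94. Class II antigen presentation had 14 of 14 genes below 0, where the median over all genes was -1.81, with 0 lower over all genes and 9 adjusted over the list alone, such as H2-Ab1 (-4.30 ± 1.07) and H2-Oa, at least 35.8-fold lower. Its call (adjusted p = 0.00496) had adjusted p = 0.748 with an estimated correlation. The tissue macrophage list had 17 of 17 below 0 and 4 adjusted over the list alone (Adgre1 -5.77 ± 1.90). The neutrophil list had 14 of 15 below 0, with 1 over all genes and 7 adjusted over the list alone, and oxidative phosphorylation had 31 of 32 below 0. These calls had adjusted p = 0.0123, 0.0123 and 0.0203, and each adjusted p = 0.748 with an estimated correlation. A fixed block for the animal gave these lists adjusted p = 0.00733, 0.136 and 0.199, so the last 2 were no longer called. Adding the mean of the sham 58 arrays to sham High left 0 genes and ended the oxidative phosphorylation call (adjusted p = 0.0567). The model without the arrays of low yield gave 61 genes (9 higher, 52 lower), and the oxidative phosphorylation median was then 0.18, with H2-Ab1 at -2.14 and Cxcr4 at -7.65. The count was 458 without High replicate 2, 11 without Low replicate 1 and 1 without Low replicate 2. A fixed block for the animal left 0 genes in limma, with 1357 at an unadjusted p under 0.05.

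In Ly6C High cells, 4 h after ischemia (n = 3) was compared with sham (n = 2), where the Gapdh 3' to 5' ratios were 2.56 to 19.7 and 28.3 to 298. The transcripts that rose most were Ifitm1 (at least 289-fold), Srp9, a signal recognition particle protein (at least 244-fold), Smim26 (at least 183-fold), Stfa2l1 (at least 179-fold), Wfdc21 (at least 156-fold) and Morrbid, a long noncoding RNA that prolongs myeloid cell survival (at least 145-fold). Pa2g4, a growth regulator, fell by 5.16 ± 1.08 on the log2 scale. Pro-inflammatory mediators were higher: 15 of 18 above 0, median 3.61 against 0.74 over all genes, with Il1b past the test over all genes (5.14 ± 1.04) and 8 adjusted over the list alone, among them Ccl4 (at least 80.5-fold), Cxcl2 (5.61 ± 1.41) and Ptgs2, which makes prostaglandins (at least 93.2-fold). The call (adjusted p = 4.20e-04) had adjusted p = 0.524 with an estimated correlation. Immediate early genes had 22 of 23 above 0 and 7 adjusted over the list alone, such as Btg2 (4.03 ± 0.99), at adjusted p = 5.64e-04, and adjusted p = 0.590 with an estimated correlation. Neutrophil genes had 14 of 15 above 0, with 1 over all genes and 6 adjusted over the list alone, such as Camp, an antimicrobial granule peptide (at least 22.8-fold). That call (adjusted p = 3.51e-04) had adjusted p = 0.250 with an estimated correlation. The mean of the pro-inflammatory list was 4.94 in sham High, 8.36 at 4 h and 8.11 over the 3 arrays labelled sham 58 High, and that of immediate early genes was 6.10, 8.86 and 9.30. The gate of those 3 arrays is in doubt: the sort marker ran from 7.75 to 12.94, and they correlated at 0.711 to 0.736 with sham Low, their highest mean with any group, and at 0.394 to 0.406 with sham High, their lowest. When their mean was added to sham High, 1 gene passed instead of 36 (Il1b 3.86, adjusted p = 0.429), while the 2 lists stayed called (medians 2.81 and 1.93).

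Further lists were called as higher at 4 h in High cells. Classical monocyte genes had 16 of 16 above 0 (median 3.72), at adjusted p = 5.64e-04, and adjusted p = 0.590 with an estimated correlation. Oxidative phosphorylation had 31 of 32 above 0 (Sdha at least 42.8-fold), at adjusted p = 2.00e-05, and adjusted p = 0.622 with an estimated correlation. The erythrocyte and platelet list had 4 of 4 above 0, with 3 adjusted over the list alone (Hbb-b2 at least 26.4-fold), at adjusted p = 0.0159, and adjusted p = 0.250 with an estimated correlation. Medians of these 3 lists were 0.35, -0.07 and 1.99 without the arrays of low yield. In limma 36 genes passed, 35 higher and 1 lower; the deposited signals gave 0 and 1. With the arrays of low yield left out 70 genes passed (44 higher, 26 lower), while Il1b (3.10, adjusted p = 0.105) and Pa2g4 (-4.41, 0.215) did not; Srp9 was then at 6.34, Cxcl2 at 3.58, Btg2 at 2.09 and Hbb-b2 at 2.01. The count was 9 without 4 h replicate 30, 10 without 4 h replicate 32 or 33, 17 without sham replicate 1 and 516 without sham replicate 2.

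In Ly6C Intermediate cells 4 h after ischemia (n = 3) 18 genes were lower than in sham (n = 2) and 0 were higher. Sham Intermediate replicate 1 had Gapdh and actin 3' to 5' ratios of 431 and 183, against at most 10.5 and 6.33 at 4 h. Lrp2, the megalin receptor of proximal tubule, fell at least 75.2-fold, Igfbp1, an insulin-like growth factor binding protein, at least 73.1-fold, and Tinag, a tubular basement membrane protein, at least 58.4-fold. Hdac2 fell at least 113-fold, Ugt8a at least 55.9-fold and Kat7, a histone acetyltransferase, at least 55.0-fold. Of the 21 kidney tubule genes 20 lay below 0 (median -1.52 against -0.09 over all genes), with Lrp2 lower over all genes and 4 adjusted over the list alone, among them Slc22a8 (-4.02 ± 1.21), Slc5a2 (-4.69 ± 1.47) and Aqp1 (at least 42.1-fold lower). The camera call (adjusted p = 4.26e-04) had adjusted p = 0.882 with an estimated correlation. Leaving out the arrays of low yield, none of which is in these groups, gave 30 genes. The count was 10 without 4 h replicate 30, 6 without 4 h replicate 32, 3 without 4 h replicate 33 and 69 without sham replicate 1.

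At 24 h Ly6C Intermediate cells (n = 3) carried transcripts that sham Intermediate cells (n = 2, replicate 1 with a Gapdh 3' to 5' ratio of 431 against at most 10.0 at 24 h) lacked. Bcl2l15, a Bcl-2 family member, rose at least 172-fold (log2 7.48 ± 0.70, adjusted p = 4.94e-05), Olr1, the LOX-1 receptor for oxidised lipoprotein, at least 128-fold and Lipg, endothelial lipase, at least 107-fold. Arg1, the arginase of alternatively activated macrophages, was at least 226-fold higher (log2 7.82 ± 1.71), with adjusted p = 0.0521 over all genes and 0.00532 adjusted over the list alone; it was the only 1 of 19 alternative activation genes past that test. Tubule transcripts fell: Slc5a12, a lactate transporter, at least 174-fold, Slc17a1, a phosphate transporter, at least 105-fold, Ces1f, a carboxylesterase, at least 102-fold, and Lrp2 at least 78.0-fold. Cnn3, a calponin, fell at least 252-fold. In the kidney tubule list 21 of 21 lay below 0 (median -4.29 against -0.07 over all genes), with 1 lower over all genes and 14 adjusted over the list alone. Slc34a1 (-6.43 ± 1.44), Slc5a2 (-6.46 ± 1.47) and Slc12a3 (at least 34.9-fold lower) were among them. The call (adjusted p = 1.07e-12) had adjusted p = 0.238 with an estimated correlation.

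Of the 38 genes that passed at 24 h in limma 3 were higher and 35 lower; the deposited signals gave 4 and 3, and centring gave 7 and 4. Leaving out the arrays of low yield gave 100 genes, with 37 of the 38 again called in the same direction. The count was 23 without 24 h replicate 8 or 9 and 78 without sham replicate 1.

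At 9 days Ly6C Intermediate cells (n = 3, 2 of them arrays of low yield) held 1 gene above sham (n = 2; Gapdh 3' to 5' ratios of 431 and 3.93 against at most 8.16 at 9 days, and actin ratios of 183 and 2.83 against 51.8 and 22.1 on the arrays of low yield and 2.00 on the other): Klf4, a transcription factor of monocyte differentiation, which rose by 5.98 ± 1.09 (log2, adjusted p = 0.0223). Several tubule transcripts were below detection on all 3 arrays. Umod, the uromodulin of the thick ascending limb, fell at least 948-fold, Spink1, a trypsin inhibitor, at least 526-fold, Miox, a proximal tubule oxygenase, at least 277-fold, and Slc34a1, the phosphate transporter of proximal tubule, at least 237-fold. Cnn3 fell at least 296-fold. In the kidney tubule list 21 of 21 lay below 0 (median -6.16 against -0.45 over all genes), with 5 lower over all genes and 20 adjusted over the list alone. The call (adjusted p = 1.75e-17) had adjusted p = 0.0856 with an estimated correlation, and the median was -5.78 without the arrays of low yield. Oxidative phosphorylation had 32 of 32 below 0 (Ndufb9 -6.30 ± 1.85), at adjusted p = 4.52e-07, and adjusted p = 0.780 with an estimated correlation; its median went from -3.38 to -1.03 without the arrays of low yield. In the neutrophil list, which was not called (adjusted p = 0.0573), Mmp8, a granule collagenase, fell by 7.48 ± 1.40. In limma 57 genes passed, 1 higher and 56 lower, against 110 (63 higher, 47 lower) without the arrays of low yield, with 34 called in the same direction in both; Cnn3 (-8.90, adjusted p = 0.103) and Mmp8 (-6.26, 0.169) then missed the threshold, and Ndufb9 was at -3.41. The count was 9 without 9 day replicate 13, 21 without 9 day replicate 8, 442 without 9 day replicate 9 and 13 without sham replicate 2.

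Ly6C Low cells at 9 days (n = 3) and in sham (n = 2) gave well-detected arrays, and 83 genes passed in limma. The sort marker averaged 11.47 in sham Low and 4.77 in 9 day Low, and whether these 2 groups hold the same gate is not settled. Higher at 9 days were Malt1, a paracaspase of NF-kB signalling, by 7.89 ± 1.40 (log2, adjusted p = 0.0132), Macf1 at least 214-fold, Lin54, a cell cycle repressor subunit, at least 117-fold, Lhfp at least 111-fold, and Olfml3, a secreted protein of microglia and macrophages, at least 66.0-fold. Cxcl1, a neutrophil chemokine, rose by 5.57 ± 1.26. Arg1 was at least 72.5-fold higher, with adjusted p = 0.0935 over all genes and 0.0139 adjusted over the list alone. The tissue macrophage list was called as higher, with 16 of 17 above 0 (median 1.32 against -0.12 over all genes), although 0 of its genes passed over all genes or adjusted over the list alone; Tmem119 was 3.24 ± 1.04 higher. That call (adjusted p = 0.0125) had adjusted p = 0.567 with an estimated correlation. Immediate early genes were called as higher, 19 of 23 above 0 (median 0.49), at adjusted p = 0.00825, and adjusted p = 0.566 with an estimated correlation.

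Neutrophil transcripts were lower in 9 day Low than in the arrays labelled sham Low, which also carried the sort marker. Stfa2l1 fell by 9.46 ± 1.10 on the log2 scale (adjusted p = 8.79e-04), Wfdc21 by 7.31 ± 0.94, G0s2 by 6.83 ± 1.18 and Il1r2, the decoy interleukin-1 receptor, by 6.37 ± 1.40. Of the 15 neutrophil genes 15 lay below 0 (median -4.81), with 3 lower over all genes and 11 adjusted over the list alone. The call (adjusted p = 1.99e-14) kept adjusted p = 0.00528 with an estimated correlation. Tubule transcripts fell too: Egf, made by the distal tubule, at least 321-fold, Dnase1, a kidney nuclease, at least 142-fold, and Defb1, an epithelial defensin, by 6.97 ± 1.16 on the log2 scale. In the kidney tubule list 21 of 21 lay below 0 (median -4.29), with 1 lower over all genes (Slc12a3, at least 65.0-fold) and 13 adjusted over the list alone, at adjusted p = 1.99e-14, and adjusted p = 0.0853 with an estimated correlation. Endothelial genes had 8 of 8 below 0, with Ramp2 (at least 16.4-fold) and Ehd3 (-3.95 ± 0.77) lower over all genes and 3 adjusted over the list alone, at adjusted p = 9.83e-04, and adjusted p = 0.0853 with an estimated correlation.

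Dendritic cell genes were lower in 9 day Low cells, with Btla (at least 19.6-fold) and Flt3 (at least 8.76-fold) past the test over all genes and 3 of 14 adjusted over the list alone. Their call (adjusted p = 0.0237) had adjusted p = 0.269 with an estimated correlation. Classical monocyte genes had 12 of 16 below 0 and 3 adjusted over the list alone, such as Chil3 (-4.79 ± 1.12), at adjusted p = 0.00201, and adjusted p = 0.566 with an estimated correlation. The 2 tested eosinophil and mast cell genes, Hdc (-6.99 ± 1.87) and Siglecf (at least 9.77-fold lower), were both below 0, at adjusted p = 0.00869, and adjusted p = 0.178 with an estimated correlation. Of the 83 genes 26 were higher and 57 lower in limma; quantile normalization gave 5 and 9, and centring gave 9 and 8. Leaving out the arrays of low yield, none of which is in these groups, gave 206 genes (53 higher, 153 lower), and the 83 were again called in the same direction. The count was 50 without Low replicate 8, 54 without Low replicate 9, 51 without sham replicate 1 and 5 without sham replicate 2.

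From 4 h to 24 h in Ly6C Intermediate cells (n = 3 each) 10 genes changed in limma, 5 higher and 5 lower. Bcl2l15 rose at least 175-fold (log2 7.45 ± 0.62, adjusted p = 9.67e-06), Mapk1ip1l by 6.61 ± 1.07, Rc3h1, an RNA-binding repressor of inflammatory transcripts, at least 84.6-fold, Lipg at least 83.2-fold and Acot1, an acyl-CoA thioesterase, by 6.18 ± 1.00. Egf fell by 7.80 ± 1.37 on the log2 scale, Slc17a1 at least 197-fold, Ugt2b38 at least 113-fold, H6pd at least 29.6-fold and Cyp2d12 at least 24.5-fold. In the kidney tubule list 18 of 21 lay below 0 (median -1.51 against -0.01 over all genes), with 0 lower over all genes and 4 adjusted over the list alone, such as Slc34a1 (-5.31 ± 1.29) and Slc12a3 (at least 30.2-fold lower). The call (adjusted p = 6.74e-05) had adjusted p = 0.761 with an estimated correlation. Arg1 was 6.10 ± 1.53 higher at 24 h, with adjusted p = 0.217 over all genes and 0.0186 adjusted over the list alone. The deposited signals gave 0 higher and 1 lower. Leaving out the arrays of low yield gave 28 genes, the count was 20 without 24 h replicate 8 and 6 without 4 h replicate 30.

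From 24 h to 9 days in Ly6C Intermediate cells (n = 3 each, 2 of the 9 day arrays of low yield) Fam120a rose by 5.72 ± 1.15 (log2) and Atmin, a DNA damage response factor, at least 8.51-fold. Smim3 fell by 8.53 ± 1.47 on the log2 scale, Mapk1ip1l at least 203-fold, Glipr2 by 7.35 ± 1.52 on the log2 scale, Spink1 at least 159-fold and Malsu1 at least 149-fold. Mmp8 fell by 7.12 ± 1.25 and Bcl2l15 at least 138-fold. The erythrocyte and platelet list had 4 of 4 below 0 (median -4.64 against -0.16 over all genes), with 0 lower over all genes and 4 adjusted over the list alone: Ppbp (at least 27.9-fold lower) and Pf4 (-7.09 ± 1.71), both platelet chemokines, and the globins Hbb-b2 and Hba-a2. That call (adjusted p = 6.21e-05) kept adjusted p = 0.0204 with an estimated correlation. Neutrophil genes had 14 of 15 below 0, with 1 over all genes and 4 adjusted over the list alone, at adjusted p = 1.66e-05, and adjusted p = 0.0973 with an estimated correlation.

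Other lists were called between 24 h and 9 days in Intermediate cells, and none kept its call with the correlation estimated. Classical monocyte genes had 14 of 16 below 0 (Mgst1 -6.34 ± 1.20 over all genes) at adjusted p = 0.00711, and adjusted p = 0.697 with an estimated correlation. Pro-inflammatory mediators had 15 of 18 below 0 and 3 adjusted over the list alone (Ccl4 -5.57 ± 1.30) at adjusted p = 0.00446, and adjusted p = 0.526 with an estimated correlation. Chemokine receptors had 7 of 9 below 0 and 2 adjusted over the list alone (Ccrl2 -4.24 ± 1.24) at adjusted p = 0.0380, and adjusted p = 0.526 with an estimated correlation. Oxidative phosphorylation (31 of 32 below 0, median -2.10) and kidney tubule (16 of 21 below 0, median -1.23) had adjusted p = 4.55e-04 and 0.0380, and each adjusted p = 0.697 with an estimated correlation. Dendritic cell genes were called as higher (13 of 14 above 0, median 0.99) at adjusted p = 0.00980, and adjusted p = 0.260 with an estimated correlation. In limma 32 genes passed, 2 higher and 30 lower, against 87 (77 higher, 10 lower) without the arrays of low yield, when the medians of the classical monocyte, pro-inflammatory and oxidative phosphorylation lists were 0.08, 0.61 and -0.04. Of the genes named, Fam120a (4.29, adjusted p = 0.0779), Atmin (3.24, 0.0763), Smim3 (-6.83, 0.182), Glipr2 (-3.88, 0.127), Mmp8 (-5.91, 0.171) and Mgst1 (-3.63, 0.0790) then missed the threshold, and Pf4, Ccl4, Ccrl2 and Hba-a2 were at -2.01, -1.54, -0.29 and -0.68. The count was 11 without 24 h replicate 7 or 8 and 16 without 24 h replicate 9. It was 6, 12 or 557 without 9 day replicate 13, 8 or 9.

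Set against 4 h, 9 day Ly6C Intermediate cells (n = 3 each) again had more Klf4, at least 33.8-fold (log2 5.08 ± 0.98, adjusted p = 0.0327). Umod fell at least 527-fold, Spink1 at least 442-fold and Kap, the androgen-regulated kidney protein, by 8.42 ± 1.78 on the log2 scale. Egf fell at least 254-fold and Stfa3, a stefin, by 7.60 ± 1.30 on the log2 scale. In the kidney tubule list 20 of 21 lay below 0 (median -3.78 against -0.21 over all genes), with 3 lower over all genes and 10 adjusted over the list alone, at adjusted p = 4.49e-09, and adjusted p = 0.275 with an estimated correlation. Neutrophil genes had 15 of 15 below 0, with Mmp8 lower over all genes (-6.40 ± 1.25) and 3 adjusted over the list alone, at adjusted p = 0.00102, and adjusted p = 0.275 with an estimated correlation. The erythrocyte and platelet list had 4 of 4 below 0, with Hbb-b2 at least 104-fold lower and 3 adjusted over the list alone, at adjusted p = 8.60e-04, and adjusted p = 0.0690 with an estimated correlation. Oxidative phosphorylation (31 of 32 below 0, Ndufb9 -6.05 ± 1.65) and pro-inflammatory mediators (16 of 18 below 0) had adjusted p = 3.86e-08 and 0.0384, with estimated-correlation adjusted p = 0.726 and 0.910; the second had a median of 0.80 without the arrays of low yield. In limma 33 genes passed, 1 higher and 32 lower, against 99 (76 higher, 23 lower) without the arrays of low yield, when Kap was at -4.25 (adjusted p = 0.0383), Ndufb9 at -3.16 and Hbb-b2 at -8.94, and Klf4 (5.62, 0.0592) and Mmp8 (-5.18, 0.223) missed the threshold. The count was 7 without 4 h replicate 30 and 0 without 4 h replicate 32 or 33. It was 1, 9 or 443 without 9 day replicate 13, 8 or 9.

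Over the 4 Ly6C Intermediate groups (sham, 4 h, 24 h and 9 days) the F test of limma asks which genes differed at any time, and 85 of 8341 passed. Bcl2l15 averaged 9.82 ± 0.23 (log2, SD, n = 3) at 24 h and between 2.34 and 2.71 in the other groups (adjusted p = 1.13e-05). Lipg followed the same course, at 9.93 ± 2.03 at 24 h and 3.18 to 3.55 elsewhere. Igfbp1 averaged 9.03 ± 0.62 in sham (n = 2) and 2.71 to 2.83 after ischemia (adjusted p = 0.00221). Fam83h and Med17, a Mediator subunit, likewise had sham means of 7.33 and 7.91 and means of 2.81 or less at the later times. Slc17a1 stood at 9.78 in sham and 10.69 at 4 h, then at 3.07 at 24 h and 3.74 at 9 days. H6pd, a pentose phosphate enzyme of the endoplasmic reticulum, went from 8.43 at 4 h to 3.54 at 24 h. Wfdc21 stayed between 12.42 and 13.72 through 24 h and was 7.71 ± 1.73 at 9 days. Dropping the arrays of low yield gave 142 genes, 52 of them shared with the 85. The count was 566 without 9 day replicate 9, 46 without 9 day replicate 8, 45 without 9 day replicate 13 and 42 without sham replicate 2.

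**Figure D3:**
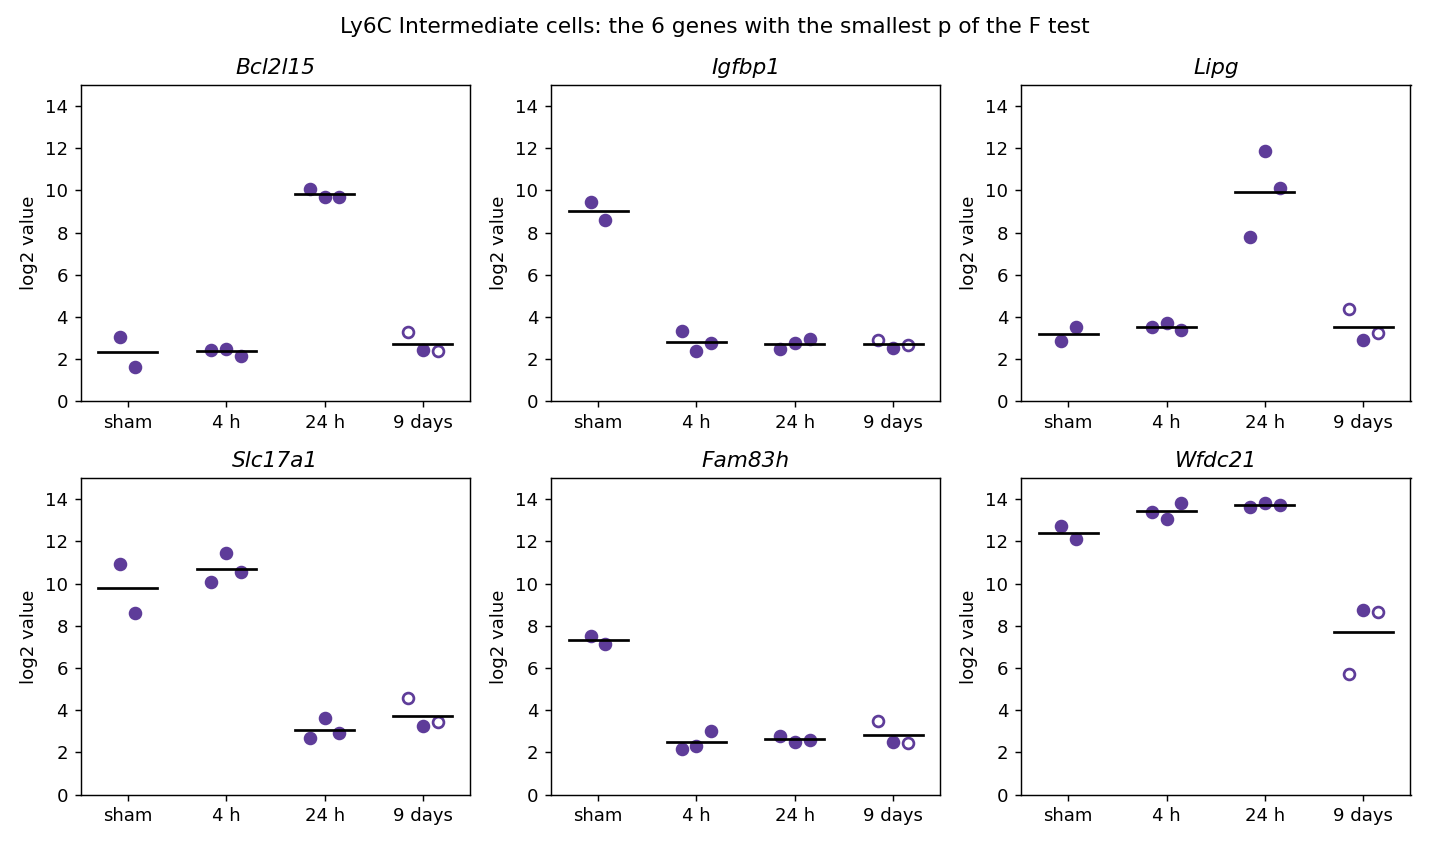
Log2 values (vertical axis) of the 6 genes with the smallest p of the F test in Ly6C Intermediate cells from sham kidneys and 4 h, 24 h and 9 days after ischemia, with a bar at each group mean and open circles for the arrays of low yield. Bcl2l15 averaged 9.82 at 24 h, and Igfbp1 averaged 9.03 in sham.

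The 4 h response of the gates was compared as a difference of effects, High minus Intermediate. Ifitm1 was the 1 gene that passed in limma (8.52 ± 1.30, adjusted p = 0.0439), while Cxcr4 (5.92 ± 1.21) and Stfa2l1 (7.51 ± 1.55) had adjusted p = 0.131. Between the gates Ifitm1 was at -9.48 in sham, and 0 genes passed at 4 h. Neutrophil (median 2.46 against 1.12 over all genes, 4 of 15 adjusted over the list alone), kidney tubule (3.76, Lrp2 alone adjusted over the list alone) and oxidative phosphorylation (3.67, 0 of 32) were called with larger differences in High cells, at adjusted p = 0.0208, 0.0101 and 8.11e-04. Each had adjusted p = 0.728 with an estimated correlation, and without the arrays of low yield their medians were 1.98, 0.36 and 0.13. These 3 lists stayed called with the animal as a fixed block, and pro-inflammatory mediators were called too (adjusted p = 0.0219). Without the arrays of low yield Cxcr4 was at 7.20 and Stfa2l1 at 7.96. The count was 2 without 4 h High replicate 33. It was 0 without 4 h High replicate 32, without any single 4 h Intermediate or sham Intermediate array, and without sham High replicate 1, or with the mean of the sham 58 arrays added. With the animal as a fixed block limma passed 0 genes, with 813 at an unadjusted p under 0.05.

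Between gates at 9 days, as a difference of effects of Intermediate minus Low, limma passed 0 genes, with 615 at an unadjusted p under 0.05; the sham Low arrays, whose label is not settled, enter this difference. Hdac2 (-9.21 ± 1.46) and Lhfp (-6.95 ± 1.15) came closest, at adjusted p = 0.0564. The neutrophil list was called as higher in this difference (median 2.29 against -0.53 over all genes, Stfa2l1 and G0s2 adjusted over the list alone), at adjusted p = 2.03e-05, and adjusted p = 0.138 with an estimated correlation. Against sham its median was below 0 in both gates, at -1.79 in Intermediate and -4.81 in Low. Dendritic cell (1.09), endothelial cell (0.98, with 0 of 8 genes detected in 9 day Intermediate) and eosinophil and mast cell (4.26) lists were called as higher at adjusted p = 0.00184, 0.00443 and 0.0240, with estimated-correlation adjusted p = 0.138, 0.170 and 0.286. Tissue macrophage (-3.23) and oxidative phosphorylation (-3.10) were called as lower at adjusted p = 0.0194 and 0.00184, and each had adjusted p = 0.702 with an estimated correlation; their medians were -0.43 and -0.31 without the arrays of low yield. The count became 12 without the arrays of low yield (Stfa2l1 8.78 among them), 24 without 9 day Intermediate replicate 9, 12 without sham Intermediate replicate 1, 4 without sham Low replicate 1 and 1 without 9 day Low replicate 9 or 13. It was 0 with the animal as a fixed block, with 498 at an unadjusted p under 0.05, and camera then also called classical monocyte as higher (adjusted p = 0.0306).

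Camera called 10 of the 24 lists in 0 of the 15 comparisons. Their smallest adjusted p was 0.0536 for interferon-stimulated genes and 0.0591 for cell cycle, both in 9 day Intermediate against 9 day Low, where Stat2 (at least 13.8-fold) and Mcm6 (at least 14.8-fold) were lower over all genes (adjusted p = 0.263 and 0.0846 without the arrays of low yield). It was 0.0888 for matrix remodelling and 0.170 for alternative activation, both in Intermediate cells at 24 h against sham, and 0.104 for hypoxia and glycolysis in Intermediate cells at 9 days against 24 h. It was 0.0953 for nonclassical monocyte and 0.101 for NK cell genes in the difference of effects at 9 days, 0.457 for T cell and 0.0831 for fibroblast genes in High cells at 4 h against sham, and 0.557 for B cell genes in the difference of effects at 4 h. Other models did call some of them: without the arrays of low yield 6 passed in at least 1 comparison (smallest adjusted p = 4.95e-04 for nonclassical monocyte, 0.00234 for hypoxia and glycolysis, 0.00391 for matrix remodelling, 0.0201 for alternative activation, 0.0211 for interferon-stimulated genes and 0.0398 for cell cycle). The covariate gave 0.0486 for interferon-stimulated genes in Low cells at 9 days against sham, besides the 2 lists named above. None of these covariate calls held with an estimated correlation (0.178 for interferon-stimulated genes). An estimated correlation was not run without the arrays of low yield. Sham 58 added to sham High gave 0.0351 for cell cycle at 4 h. The rotation test fry called NK cell genes (smallest adjusted p = 7.70e-04) and 5 of those 6 lists.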

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

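The tests of array yield on the median over all genes, on neutrophil transcripts and on tubule transcripts in Intermediate cells, the counts of list members on either side of 0, and the model without the arrays of low yield were chosen after the results were seen. The splits of the arrays and the test of the tubule list in Low cells with the share of probe sets present as a covariate were set before.

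Responses that differed between gates at 4 h, by a test of the difference itself (High minus Intermediate), were those of Ifitm1 (8.52 on the log2 scale) and of the oxidative phosphorylation (median 3.67), neutrophil (2.46) and kidney tubule (3.76) lists. At 9 days (Intermediate minus Low) they were those of tissue macrophage (-3.23), oxidative phosphorylation (-3.10), neutrophil (2.29), dendritic cell (1.09), eosinophil and mast cell (4.26) and endothelial cell (0.98, with 0 of 8 genes detected in 9 day Intermediate) lists. None of these list calls passed with an estimated correlation. Groups in these differences hold the 3 arrays of low yield; without them, which leaves 1 array each in sham High and 9 day Intermediate, the values at 4 h were 8.28 for Ifitm1, 0.13 for oxidative phosphorylation, 1.98 for neutrophil and 0.36 for kidney tubule, and the calls of oxidative phosphorylation and kidney tubule ended (adjusted p = 0.978 each). At 9 days they were -0.43, -0.31, 4.18, 1.99, 8.15 and 0.59 in the order above, and the calls of tissue macrophage (adjusted p = 0.569) and endothelial cell (0.439) ended. Ifitm1 kept its call without 4 h High replicate 30 or sham High replicate 2, and had adjusted p from 0.0543 to 0.153 without any other single array of the 4 groups. The gates share animals, and its adjusted p was 0.336 with the animal as a fixed block and 0.0517 as a random one, so its call ended with either.

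Among the 3 arrays that share the label sham 58, which no comparison used, at least 1 had a list mean above the highest of the 6 sham arrays for 16 of the 24 lists, and none did for the other 8. All 3 arrays were above it for nonclassical monocyte, 2 for interferon-stimulated and immediate early genes, and 1 for each of the other 13 lists. The highest of the 3 had list means (log2) of 8.64 for nonclassical monocyte (highest sham array 7.93), 10.13 for tissue macrophage (10.03), 10.98 for antigen presentation (10.83) and 9.51 for pro-inflammatory mediators (8.89). They were 8.42 for alternative activation (7.88), 9.23 for chemokine receptors (8.30), 8.31 for interferon-stimulated genes (7.05), 9.45 for hypoxia and glycolysis (9.33) and 9.05 for efferocytosis (8.77). Further means were 7.42 for cell cycle (6.32), 10.00 for immediate early genes (9.30), 11.35 for neutrophil (11.13), 5.96 for NK cell (5.60), 5.89 for B cell (5.41), 7.42 for dendritic cell (7.34) and 9.99 for eosinophil and mast cell (8.60). Their shares of probe sets present ran from 29.3% to 33.6%.

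Most genes were lower in 9 day Intermediate than in 9 day Low cells, with a median log2 difference of -1.24. The median was -0.13 without the arrays of low yield, which leaves 1 Intermediate array in this comparison. Low yield of those arrays may therefore account for the broad shift. A true difference in RNA content between the gates was not tested and stays open.

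Kidney tubule transcripts were lower at 9 days than in sham in both gates. In Intermediate cells a trend with array yield as the whole cause is argued against: with the share of probe sets present as a covariate the median of the list was -4.97 (upper quartile -3.94, camera adjusted p = 2.83e-17, and 0.0898 with an estimated correlation), against -6.16 without it. In Low cells the groups differed little in share (31.8% ± 6.04 and 33.7% ± 8.92), which argues against a difference in yield there, and the covariate gave -4.31 (upper quartile -2.60) against -4.29. Less RNA of tubule cells carried into the sorted cells stays open: that 21 of 21 tested members lay below 0 in both gates restates the pattern and decides nothing. Umod averaged 12.80 in sham Intermediate and 2.92 at 9 days, and Miox 10.55 in sham Low and 3.86 at 9 days. The CD11b gate is meant to exclude tubule cells, but the purity of the sort was not tested. In sham Intermediate 21 of 21 tubule genes were detected on both arrays, with a list mean of 10.08. None of the 21 genes is in another list (0 shared). Lower expression of these genes in tubules after ischemia, which the groups also differ by, was not tested and stays open.

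Neutrophil transcripts were higher in 9 day Intermediate than in 9 day Low cells. With the share of probe sets present as a covariate, which keeps all arrays, the median of the list was 4.31, against 2.81 without it. The lower quartile was 2.01, and camera gave adjusted p = 6.78e-11, or 0.0187 with an estimated correlation. This does not decide on array yield as the cause. Intermediate had the lower mean share (11.1% against 31.8%), and the covariate moved lists such as tissue macrophage upwards (-3.37 to -0.54). Some lists went the other way, such as endothelial cell (0.48 to 0.06). A rise of the neutrophil median was therefore likely in advance. The value without the arrays of low yield, 5.01, rests on 1 Intermediate array. Neutrophils, or their RNA, in the Intermediate gate stay open: that 14 of 15 members lay above 0 restates the pattern, and the member below 0 was the granule gene Mmp8. Neutrophils carry CD11b and an intermediate level of Ly6C, so the sort would not remove them; 3 of the 15 genes are also in another list. Expression of these genes by monocytes of this gate was not tested and stays open.

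The 6 arrays of a comparison can be divided in only 10 ways, too few for a share under 0.05. For 4 h High against Intermediate the real division gave 0 genes and the highest other 5, so 10 of 10 gave as many; among the 4 that part all pairs of the same animal the highest other gave 2. For 9 day Intermediate against Low the real one gave 52 and the highest other 39 (1 of 10 gave as many), and that other one put both Intermediate arrays of low yield with 1 Low array; among the 4 that part all pairs the highest other gave 15. For 24 h against 4 h both the real one and another gave 10 (2 of 10). For 9 days against 24 h the real one gave 32 and the highest other 221 (3 of 10 gave as many), which left both arrays of low yield with 1 array at 24 h; so many calls point to a structure of the samples by yield. For 9 days against 4 h the real one gave 33 and the highest other 107 (2 of 10), again with both arrays of low yield on 1 side. The counts without those arrays were 27, 87 and 99 in the 3 comparisons that hold them.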

How the results depend on the processing

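The models without the 3 arrays of low yield and with the share of probe sets present as a covariate were chosen after the detection calls were seen, and the list tests with this covariate or with sham 58 after the results; the other alternatives were planned. Of 168 results for single named genes (109 genes) under each alternative that applies to them (55 of them for the fixed block, 37 for sham 58, those of the groups concerned for each array left out, and none for removal of other-cell-type genes), 3069 values in all, 2226 kept their direction and their side of the threshold, 725 kept the direction and lost the threshold, 118 passed it only under the alternative and 0 reversed. Genes were named for large differences or small p, so reversals were unlikely. Of 317 gene counts, 126 were within 1.5 times the count reported and 191 were not. Causes of moved counts were not tested unless named here. The number and yield of the arrays limit the precision.

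Counts that moved by more than 1.5 times were as follows. The deposited signals gave 0 for 9 day Intermediate against Low, sham High against Intermediate, sham Intermediate against Low, sham High against Low, 4 h against sham in Intermediate, 9 days against sham in Intermediate, 9 days against 24 h and the difference of effects at 4 h, 1 for 4 h against sham in High and 24 h against 4 h, 7 for 24 h against sham, 21 for 9 days against sham in Low, 2 for 9 days against 4 h and 11 for the F test. Quantile normalization of the 21 arrays gave 15 for 9 day Intermediate against Low, 1 for sham Intermediate against Low, 8 for 4 h against sham in High, 9 for 4 h against sham in Intermediate, 14 for 9 days against sham in Low, 58 for 9 days against 24 h, 2 for the difference of effects at 4 h and 4 for the difference of effects at 9 days. Centring each array on its median, which moved the median difference over all genes from -1.24 to 0.34 in 9 day Intermediate against Low, from -0.58 to 0.76 in sham Intermediate against Low and from -0.09 to 0.46 in 4 h against sham in Intermediate, gave 2 for 9 day Intermediate against Low and sham High against Intermediate, 1 for sham Intermediate against Low, 0 for sham High against Low, 4 h against sham in Intermediate, 9 days against sham in Intermediate and the difference of effects at 4 h, 5 for 4 h against sham in High, 11 for 24 h against sham, 17 for 9 days against sham in Low, 184 for 9 days against 24 h, 148 for 9 days against 4 h and 158 for the F test. Testing genes without a filter on detection gave 91 for 9 day Intermediate against Low, 37 for sham Intermediate against Low, 57 for sham High against Low, 11 for 4 h against sham in High, 142 for 9 days against sham in Low, 17 for 9 days against 4 h and 23 for the difference of effects at 9 days. Requiring detection on every array of a group gave 0 for sham Intermediate against Low and the difference of effects at 4 h. The mean of the probe sets of a gene gave 145 for 9 day Intermediate against Low, 43 for sham Intermediate against Low and sham High against Low, 70 for 24 h against sham, 100 for 9 days against sham in Intermediate, 163 for 9 days against sham in Low, 8 for the difference of effects at 4 h and 13 for the difference of effects at 9 days. Fitting only the groups compared, with fewer arrays to estimate the spread, gave 0 for 9 day Intermediate against Low, sham High against Intermediate, sham Intermediate against Low, sham High against Low, 4 h against sham in High, 4 h against sham in Intermediate, 24 h against sham, 9 days against sham in Intermediate and the difference of effects at 4 h, 5 for 24 h against 4 h, 8 for 9 days against 24 h, 2 for 9 days against 4 h and 49 for the F test. Array weights gave 13 for 4 h High against Intermediate, 1759 for 9 day Intermediate against Low, 4 for sham High against Intermediate, 8 for 4 h against sham in High, 67 for 24 h against sham, 356 for 9 days against sham in Intermediate, 302 for 9 days against sham in Low, 29 for 24 h against 4 h, 602 for 9 days against 24 h, 572 for 9 days against 4 h, 0 for the difference of effects at 4 h and 523 for the F test. A variance trend with a robust prior gave 39 for sham Intermediate against Low, 22 for sham High against Low, 8 for 4 h against sham in High, 144 for 9 days against sham in Low, 17 for 9 days against 24 h, 11 for 9 days against 4 h, 0 for the difference of effects at 4 h and 14 for the difference of effects at 9 days. The share of probe sets present as a covariate gave 1 for 9 day Intermediate against Low, 8 for sham High against Intermediate, 0 for sham Intermediate against Low, sham High against Low and the difference of effects at 4 h, 6 for 4 h against sham in High, 60 for 24 h against sham, 30 for 9 days against sham in Intermediate, 110 for 9 days against 24 h, 51 for 9 days against 4 h and 2 for the difference of effects at 9 days. Leaving out the 3 arrays of low yield gave 27 for 9 day Intermediate against Low, 72 for sham High against Intermediate, 45 for sham Intermediate against Low, 61 for sham High against Low, 70 for 4 h against sham in High, 30 for 4 h against sham in Intermediate, 100 for 24 h against sham, 110 for 9 days against sham in Intermediate, 206 for 9 days against sham in Low, 28 for 24 h against 4 h, 87 for 9 days against 24 h, 99 for 9 days against 4 h, 31 for the difference of effects at 4 h, 12 for the difference of effects at 9 days and 142 for the F test. The animal as a fixed block gave 0 for 9 day Intermediate against Low, sham High against Intermediate, sham Intermediate against Low, sham High against Low and the difference of effects at 4 h. The animal as a random block gave 0 for the difference of effects at 4 h. Adding the mean of the 3 arrays of sham 58 to sham High gave 16 for sham High against Intermediate, 0 for sham High against Low and the difference of effects at 4 h and 1 for 4 h against sham in High.

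Gene list counts moved too. With the correlation estimated camera called 1 for 9 day Intermediate against Low, 9 days against sham in Low and 9 days against 24 h. It called 0 elsewhere. Fry called 5 for 9 day Intermediate against Low, 16 for sham High against Low, 0 for 4 h against sham in Intermediate and the difference of effects at 9 days, 2 for 9 days against 24 h and 1 for the difference of effects at 4 h. Without the arrays of low yield camera called 3 for 4 h High against Intermediate and 9 days against 4 h, 4 for sham High against Intermediate and 24 h against 4 h, 9 for sham High against Low, 7 for 24 h against sham, 6 for 9 days against sham in Intermediate and 10 for the difference of effects at 9 days. With a fixed animal block it called 2 for 4 h High against Intermediate and sham High against Low. Removing the genes of other-cell-type lists kept each count of genes within 1.5 times. The tubule list lacks Slc5a12 and Slc17a1, so tubule genes stayed in the counts. All 63 called list medians kept their sign with the deposited signals, quantile normalization and centring.

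Leaving out each array of the groups compared in turn gave ranges of genes of 0 to 4 for 4 h High against Intermediate, 8 to 1290 for 9 day Intermediate against Low, 10 to 386 for sham High against Intermediate, 0 to 12 for sham Intermediate against Low, 1 to 458 for sham High against Low, 9 to 516 for 4 h against sham in High, 3 to 69 for 4 h against sham in Intermediate, 23 to 78 for 24 h against sham, 9 to 442 for 9 days against sham in Intermediate, 5 to 65 for 9 days against sham in Low, 6 to 20 for 24 h against 4 h, 6 to 557 for 9 days against 24 h, 0 to 443 for 9 days against 4 h, 0 to 189 for the difference of effects at 4 h, 0 to 24 for the difference of effects at 9 days and 42 to 566 for the F test. Leaving out 1 array of a sham group leaves a lone array, and leaving out the arrays of low yield leaves 1 each in sham High and 9 day Intermediate; a lone array is then assumed to vary like the other groups.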

Other observations

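Arg1, singled out here after its values were seen, was measured at 10.40, 10.55 and 10.87 (log2) on the 3 arrays of 24 h Intermediate, and at 9.70, 9.43 and 8.00 on those of 9 day Low. In 9 day Intermediate it was at 11.19 on replicate 9, and at 5.39 and 3.33 on the arrays of low yield. On the 6 arrays at 4 h it reached 7.68 on Intermediate replicate 32 and lay at 4.26 or below on the others. The sham arrays lay at 4.38 or below, and the 3 arrays of sham 58 at 3.37, 8.01 and 7.47.

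Tissue macrophage genes averaged 11.01 ± 0.46 (log2, SD, n = 3) in 9 day Low and 9.73 ± 0.43 (n = 2) in sham Low. Means were 8.67 in sham Intermediate, 8.25 in 4 h Intermediate, 8.07 in 4 h High and 7.57 in 24 h Intermediate. In 9 day Intermediate they were 10.11 on replicate 9 and 6.22 and 5.53 on the arrays of low yield (mean 7.29), and in sham High 7.42 on 1 array and 4.14 on the array of low yield (mean 5.78).

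The 3 arrays of sham 58 correlated with each other at 0.707 to 0.764 across genes, at 0.711 to 0.736 on average with sham Low (the highest of the 8 groups for each) and at 0.394 to 0.406 with sham High (the lowest, which holds an array of low yield). The probe set of Ly6c1 and Ly6c2 read 7.75 on the lowest and 12.94 on the highest of them. The reference RNA had 69.6% of probe sets present.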
